A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

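RNA of a hal4hal5 double mutant and of its wild type was compared on 12 two-colour spotted arrays, with 1 strain labelled in Cy3 and the other in Cy5 on each array. The labels place 4 arrays in each of 3 groups, namely the BY4741 background in YPD at pH 4.5, the W303 background in YPD at pH 4.5 and the W303 background in YPD at pH 6.0, and the design text calls the 4 arrays of a group biological replicates. Cells were harvested in log phase, and poly-dT primed aminoallyl cDNA was coupled to the dyes, per the labels. Whether the wild-type RNA of 1 culture was used on more than 1 array is not given in the sources used here.

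The deposited values are read here as a log2 ratio of the 2 dyes, with 1 value for each of 5994 open reading frames on each array. The base of the logarithm is not given in the sources used here. Base 2 was taken from the range of the values, -7.15 to 5.55, and the natural logarithm cannot be excluded, in which case every log2 value and fold printed here would be too small in size. The authors' normalisation and filter are not described in the sources used here, but each array median lies within 0.035 of 0 and repeat spots had been merged. No scanner intensities were used here, so signal over background is unknown for every value. An array carries between 4418 and 5696 values. The number of arrays, 4 in each group, limits the precision.

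The direction of the ratios was settled by a rule fixed before the data were examined. Within the groups, 10 of the 11 pairs of arrays with opposite dye orientation correlated negatively across genes as deposited, with r between -0.914 and 0.0906, so the columns follow the dyes rather than the strains. Which dye is the numerator does not show in these correlations. Cy5 over Cy3 was taken because, with the sign turned on the arrays with the mutant in Cy3, SAT4 was lower in the mutant on 9 of the 10 arrays that measured it and HAL5 on 9 of 11, and Cy3 over Cy5 would make them higher on the same arrays. The direction of every ratio thus rests on the small ratios of the deleted genes alone, which are no finding about it. The mutant was in Cy5 on 7 arrays. Orientation was balanced in BY4741 and in W303 at pH 6.0, and 3 to 1 in W303 at pH 4.5.

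Each group was tested with limma 3.58.1 in R 4.3.3, as a fit of 1 mean per gene with empirical Bayes moderation, in place of the one-class SAM that the design text names. Genes needed a value on at least 3 of the 4 arrays. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in the comparison. The difference between W303 and BY4741 at pH 4.5, and that between pH 6.0 and pH 4.5 in W303, were tested as contrasts of group means in 1 fit of all 12 arrays, for genes with at least 3 values in every group. All tests are two-sided. Standard errors (SE) are the moderated ones of limma, and standard deviations (SD) are those between arrays. The p-values of single genes rest on the spread between these arrays, pooled over all 12 for the differences. The main p-values of gene lists, described next, compare members with other genes instead.

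A set of 39 gene lists and 5 marker lists was fixed before the data were examined, and 43 of the 44 had measured members; the mitochondrially encoded genes had 0 in the table. Each list was compared with all other genes by the pre-ranked form of camera with a preset inter-gene correlation of 0.01, and adjusted within a comparison. No list reached an adjusted p below 0.05 in any comparison with a correlation estimated from the arrays. That form used the 3678 genes measured on all 12 arrays, or the genes complete within a group. It also takes its degrees of freedom from the few arrays, which limits what it can call. A larger correlation is not always what removes a call. For the respiratory chain in W303 at pH 4.5 the estimate was 0.0085, below the preset, with an adjusted p of 0.254. Every list call printed here thus rests on the preset form of the test. Calls adjusted over the list alone are given beside those over all genes.

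Genes to name were chosen by a rule also fixed before the data were examined. It takes the deleted genes, the 10 called genes with the largest rise and the 10 with the largest fall in each group among those with 1 sign on every array that measured them, the 10 largest called differences, up to 4 called members of each list, and the auxotrophic markers. The deleted genes, the auxotrophic markers (HIS3 and ADE2 among them) and genes with only a systematic name were left out of the rankings. Of the genes the rule took for the lists and the differences between groups, those printed were picked after their values were seen, and so were the neighbours of HIS3. Names came from a table pairing 5481 of the 5994 open reading frames with RefSeq locus tags, 4994 of them with a symbol, while 513 stayed unmatched. No genome build is named in the sources used here, and coordinates of the RefSeq table served only to order the genes around HIS3. Probes of near-identical genes can share signal, so values of ribosomal protein pairs, IMD2 and IMD3, HSP82 and HSC82, and PHO5 and PHO3 are uncertain for the single member.

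The pipeline was tested in 1 run on simulated data with the missing values and spread of each gene in each group. Noise was drawn independently between genes and equally for the arrays of a group, without a dye effect, and few genes were changed. The real arrays differ from this setting, so the shares that follow hold for the simulated data only. Of genes changed by 1 on the log2 scale, 91% were recovered in BY4741, 100% in W303 at pH 4.5 and 66% in W303 at pH 6.0. Among calls, 5.49%, 4.52% and 7.41% were false in these groups. For the differences the share was 2.31% between the backgrounds and 25.4% between the pH values, where the shared spread understates that of the pH 6.0 arrays.

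Alternatives tried were median centring, scaling between arrays, stricter and looser filters on missing values, dye terms, a joint fit, robust moderation, array weights, SAM, a minimum fold of 1.5, a replicate block, other list tests, columns left unturned, and each array left out in turn. Fits with 1 array left out took genes with at least 2 values in a group, against at least 3 in the main fits. The median over repeat spots was not run, since each open reading frame has 1 value.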

Results

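The transcriptome of Saccharomyces cerevisiae lacking HAL4 (SAT4, YCR008W) and HAL5 (YJL165C), which encode related protein kinases that promote potassium uptake, was compared with that of the wild type on 12 two-colour arrays. The arrays form 3 sets of 4, for the laboratory strain BY4741 at pH 4.5 and the laboratory strain W303 at pH 4.5 and at pH 6.0, all in YPD, a rich glucose medium. The question set by the labels is which genes are expressed differently in the mutant in each set. Arrays held 5166 to 5696 values in BY4741, 5429 to 5659 in W303 at pH 4.5 and 4418 to 5652 in W303 at pH 6.0. Across genes, which are not independent replicates, the median correlation between arrays of a set was 0.623 in BY4741, 0.908 in W303 at pH 4.5 and 0.487 in W303 at pH 6.0. The array of W303 pH 6.0 replicate 3 had the fewest values, and its mean correlation with the other 3 arrays of its set was 0.186. Ratios are mutant over wild type throughout, with a direction set by the deleted genes, on a log2 scale whose base was inferred.

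Signal for the deleted genes was lower in the mutant on most arrays, by small amounts. SAT4 had a log2 ratio of -0.73 and -0.96 on the 2 BY4741 arrays that measured it, below the minimum of 3 arrays, and -0.84 ± 0.11 (SE, n = 2, adjusted p = 0.0081) in a fit of all genes with at least 2 values. Its mean was -0.17 ± 0.059 (SE, n = 4, adjusted p = 0.028) in W303 at pH 4.5 and -0.46 ± 0.37 (SE, n = 4, adjusted p = 0.56) at pH 6.0. The SAT4 call at pH 4.5 was lost without replicate 2, 3 or 4, where the mean was -0.17, -0.15 and -0.17. HAL5 had a mean of -0.51 ± 0.13 (SE, n = 4, adjusted p = 0.027) in BY4741, -0.10 ± 0.12 (SE, n = 4, adjusted p = 0.48) in W303 at pH 4.5 and -0.03 ± 0.13 (SE, n = 3, adjusted p = 0.94) at pH 6.0. Without replicate 1, 3 or 4 of BY4741 the HAL5 mean was -0.41, -0.49 and -0.45 and was no longer called, and without replicate 1 of W303 at pH 4.5 it was -0.27 with an adjusted p of 0.0089. Higher signal in the mutant was seen for HAL5 on the arrays labelled W303 pH 4.5 replicate 1 (0.42) and W303 pH 6.0 replicate 1 (0.19), and for SAT4 on the array labelled W303 pH 6.0 replicate 2 (0.62).

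Among the auxotrophic marker genes, HIS3, which encodes a histidine biosynthesis enzyme, rose in W303 by 2.00 ± 0.067 (SE, n = 4, adjusted p = 8.8e-08) at pH 4.5 and by 2.33 ± 0.18 (SE, n = 4, adjusted p = 0.0074) at pH 6.0, on all 4 arrays of each set. In BY4741 its mean was 0.15 ± 0.078 (SE, n = 4, adjusted p = 0.20). DED1, an RNA helicase gene and the next named gene beyond HIS3, had means of -0.39, 1.10 and 1.71 in BY4741, W303 at pH 4.5 and W303 at pH 6.0, and all 3 were called. MET17, which encodes the sulphide-incorporating step of sulphur assimilation, rose by 1.90 ± 0.10 (SE, n = 4, adjusted p = 9.0e-07) in W303 at pH 4.5, with means of 0.13 in BY4741 and 0.59 (adjusted p = 0.062) in W303 at pH 6.0. Genotypes at the marker genes were not used here, and a ratio near 0 can also come from a gene that mutant and wild type both lack. ADE2, a purine biosynthesis gene, fell in all 3 sets, with log2 ratios of -0.57, -2.30 and -1.11. At pH 6.0 the calls of HIS3, DED1 and ADE2 were lost without replicate 1 (2.29, 1.64 and -1.10, each with adjusted p = 0.145) or replicate 4 (2.33, 1.63 and -1.12, each with adjusted p = 0.085). LEU2 was measured on only 1 BY4741 array, replicate 4, with a log2 ratio of 5.01, and its means in W303 were 0.44 (adjusted p = 5.8e-04) at pH 4.5 and 0.24 (adjusted p = 0.35) at pH 6.0.

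**Figure D1:**
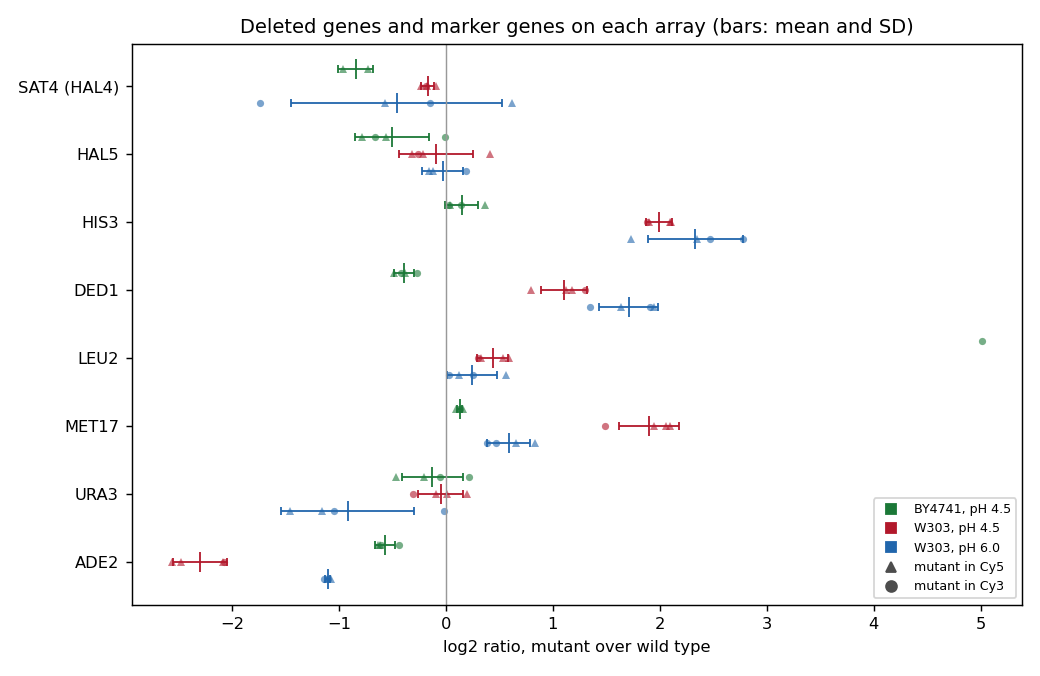
Log2 ratio of mutant over wild type for the deleted genes SAT4 and HAL5, for HIS3 and its neighbour DED1, and for other auxotrophic marker genes, with 1 point per array, triangles for arrays with the mutant in Cy5, circles for arrays with the mutant in Cy3, and bars for the mean and SD of each set. HIS3 lies between 1.73 and 2.78 on the 8 W303 arrays and between 0.03 and 0.37 on the 4 BY4741 arrays.

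In BY4741 at pH 4.5, GPG1 (YGL121C), proposed to encode a G-protein subunit, had the largest rise of the genes ranked, which leave out the auxotrophic markers in every set. It rose 6.07-fold (log2 2.60 ± 0.23 SE, n = 4, adjusted p = 7.2e-04). YGP1 (YNL160W), a secreted glycoprotein gene induced on nutrient limitation, rose 5.44-fold (log2 2.44 ± 0.064 SE, n = 4, adjusted p = 2.4e-05), NQM1 (YGR043C), a transaldolase gene, 5.23-fold, and HSP12 (YFL014W), a small heat shock protein gene, 4.38-fold. STR3 (YGL184C), a cystathionine lyase gene, rose 5.28-fold (n = 3), and PUT1 (YLR142W), for proline oxidase, 4.19-fold (n = 3). The copper regulator CUP2 (n = 3), YRO2, the ATP synthase gene ATP19 and the cell wall gene SPI1 rose 3.69-fold, 3.43-fold, 3.29-fold and 3.22-fold. SPI1 was no longer called without replicate 1 (log2 1.51, adjusted p = 0.058) or without replicate 3 (log2 1.86, adjusted p = 0.062).

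The largest fall of the ranked genes in BY4741 was that of SIT1 (YEL065W), a siderophore iron transporter gene, which was 6.19-fold lower (log2 -2.63 ± 0.33 SE, n = 4, adjusted p = 0.0026). ARO9 (YHR137W), an aromatic aminotransferase gene, was 4.79-fold lower (log2 -2.26 ± 0.10 SE, n = 4, adjusted p = 9.6e-05). The membrane transporters AQR1 (YNL065W), PDR5 (YOR153W), BAP2 (YBR068C) and TPO1 (YLL028W) had log2 ratios of -2.03, -2.0, -1.92 and -1.52. LEU1 (YGL009C), of leucine biosynthesis, had a log2 ratio of -1.73, the glycine cleavage gene GCV2 (YMR189W) of -1.56, the peroxidase gene GPX2 (YBR244W) of -1.53 and the serine deaminase gene CHA1 (YCL064C) of -1.44. All 20 of these leading genes had 1 sign on every array that measured them, as the rule for naming them requires. In all, 1714 of 5461 genes were called by limma, 871 higher and 843 lower in the mutant, and 104 of them by at least 2-fold, 79 higher and 25 lower. Requiring a 1.5-fold change left 358, 248 higher and 110 lower, and leaving out replicate 3 or replicate 4 left 754 and 986.

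Mitochondrial energy genes were higher as groups in the BY4741 mutant. Of 33 measured genes of the nuclear-encoded respiratory chain and ATP synthase, 30 rose and 0 fell (31 and 0 adjusted over the list alone), with a list median of 0.93 (adjusted p = 4.1e-18, and adjusted p = 0.468 with an estimated correlation). Examples are COX7 (1.61 ± 0.11 SE, n = 3), QCR8 (1.48 ± 0.092 SE, n = 4) and QCR7 (1.47 ± 0.071 SE, n = 4). Of 16 genes of the tricarboxylic acid cycle, 10 rose and 0 fell (11 and 1 adjusted over the list alone). The median was 0.48 (adjusted p = 4.0e-05, and adjusted p = 0.498 with an estimated correlation). Among them were SDH4 (1.38) and SDH2 (1.06). Mitochondrial ribosomal protein genes rose in 29 of 61 cases and fell in 0 (32 and 0 adjusted over the list alone). Their median was 0.24 (adjusted p = 2.8e-08, and adjusted p = 0.468 with an estimated correlation). MRPL37 (0.67) had the largest rise.

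Stress, sulphur and nitrogen genes of BY4741 were higher as groups too. In the general stress response, 16 of 38 genes rose and 1 fell (17 and 2 adjusted over the list alone). The median was 0.41 (adjusted p = 3.3e-06, and adjusted p = 0.607 with an estimated correlation). In methionine and sulphur assimilation, 14 of 32 genes rose and 3 fell (15 and 3 adjusted over the list alone). Their median was 0.20 (adjusted p = 3.8e-04, and adjusted p = 0.609 with an estimated correlation). MET16 (1.47, n = 3) and MET5 (1.36) are examples. Nitrogen catabolite repressed genes, used when good nitrogen sources are scarce, rose in 8 of 19 cases and fell in 1 (9 and 1 adjusted over the list alone). The median was 0.25 (adjusted p = 0.0089, and adjusted p = 0.468 with an estimated correlation). PUT1 and CAR2 (1.19) rose most.

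Biosynthetic and iron uptake groups were lower in BY4741. Purine and one-carbon genes fell in 16 of 18 cases and rose in 0 (17 and 0 adjusted over the list alone). Their median was -0.71 (adjusted p = 1.9e-11, and adjusted p = 0.468 with an estimated correlation). GCV2 and the near-identical IMP dehydrogenase genes IMD3 (-1.26) and IMD2 (-1.19), whose single values are uncertain, are examples. Of 42 amino acid biosynthesis genes under the activator Gcn4, 19 fell and 5 rose (23 and 7 adjusted over the list alone). The median was -0.23 (adjusted p = 0.0036, and adjusted p = 0.607 with an estimated correlation). HIS4 (-1.31) and BAT1 (-1.22) fell most. Iron regulon genes fell in 8 of 20 cases and rose in 0 (9 and 0 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.0042, and adjusted p = 0.623 with an estimated correlation). SIT1 and the iron permease gene FTR1 (-1.42) are examples. Sterol biosynthesis genes fell in 12 of 27 cases and rose in 0 (14 and 0 adjusted over the list alone). The median was -0.20 (adjusted p = 0.0031, and adjusted p = 0.623 with an estimated correlation). Members include ERG13 (-0.71) and HMG1 (-0.66). Potassium and sodium transport genes, the group closest to the deleted kinases, were not called as a list (3 of 19 rose and 5 fell, 5 and 6 adjusted over the list alone, median 0.01, adjusted p = 0.88), although the potassium transporter gene TRK2 (log2 -0.77) and QDR2 (-0.84), a drug and potassium exporter gene, fell. Of the 43 lists, 14 were called higher and 8 lower.

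The same comparison in W303 at pH 4.5 again had GPG1 at the top. GPG1 rose 27.1-fold (log2 4.76 ± 0.17 SE, n = 4, adjusted p = 1.0e-07), the small heat shock gene HSP26 (YBR072W) 23.6-fold (log2 4.56 ± 0.15 SE, n = 4, adjusted p = 8.6e-08), SPI1 (YER150W) 21.6-fold (log2 4.43 ± 0.14 SE, n = 4, adjusted p = 7.4e-08) and HSP12 18.0-fold (log2 4.17 ± 0.083 SE, n = 4, adjusted p = 2.0e-08). FLO11 (YIR019C), a flocculin gene for cell adhesion, rose 16.5-fold (log2 4.04 ± 0.41 SE, n = 3, adjusted p = 7.2e-05). HSP32 (YPL280W), of a chaperone family with near-identical members, rose 12.3-fold, the desiccation gene SIP18 (YMR175W) 10.4-fold, NQM1 9.18-fold, the alpha-factor gene MF(ALPHA)1 (YPL187W) 8.33-fold (n = 3) and ADR1 (YDR216W), an activator of glucose-repressed genes, 7.51-fold (n = 3).

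Falls in W303 at pH 4.5 are given for the 10 highest-ranked genes, again without the auxotrophic markers. ADE17 (YMR120C) was 6.05-fold lower (log2 -2.60 ± 0.099 SE, n = 4, adjusted p = 1.5e-07), ADE1 (YAR015W) 5.49-fold, ADE13 (YLR359W) 5.10-fold and ADE57 (YGL234W) 4.25-fold, and HPT1 (YDR399W), for purine salvage, 4.04-fold lower. The amino acid and peptide permeases BAP2 and PTR2 (YKR093W) had log2 ratios of -2.39 and -1.91. LEU1 (-2.17), ARO9 (-1.97) and CHA1 (-1.84) completed these 10. By the rule for naming them, each of these 20 genes had 1 sign on every array that measured it. In total, 3807 of 5501 genes were called by limma, 1988 higher and 1819 lower, and 333 of them by at least 2-fold, 266 higher and 67 lower. Requiring a 1.5-fold change left 1119, 648 higher and 471 lower.

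Stress and carbon reserve genes were higher as groups in W303 at pH 4.5. In the general stress response, 33 of 42 genes rose and 4 fell (34 and 4 adjusted over the list alone). Their median was 1.46 (adjusted p = 4.9e-10, and adjusted p = 0.442 with an estimated correlation). Trehalose and glycogen genes rose in 16 of 19 cases and fell in 1 (16 and 1 adjusted over the list alone). The median was 1.03 (adjusted p = 3.5e-06, and adjusted p = 0.442 with an estimated correlation). PGM2 (2.71 ± 0.088 SE, n = 4), GDB1 (2.53) and GLC3 (2.20) had the largest rises. In glycolysis and fermentation, 17 of 21 genes rose and 2 fell (17 and 2 adjusted over the list alone). Their median was 0.55 (adjusted p = 6.2e-04, and adjusted p = 0.539 with an estimated correlation). The hexose kinase genes GLK1 (2.58) and HXK1 (2.26) rose most.

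Mitochondrial, sulphur and nitrogen genes rose there as well. For the respiratory chain and ATP synthase, 31 of 34 genes rose and 2 fell (31 and 2 adjusted over the list alone). The median was 0.69 (adjusted p = 6.2e-08, and adjusted p = 0.254 with an estimated correlation). NDI1, for NADH dehydrogenase, rose by 1.69 ± 0.071 (SE, n = 4), whereas CYC1, for cytochrome c, fell by 1.05 ± 0.094 (SE, n = 4). The tricarboxylic acid cycle had 15 of 17 genes higher and 2 lower (15 and 2 adjusted over the list alone). Their median was 0.52 (adjusted p = 4.1e-04, and adjusted p = 0.442 with an estimated correlation). Members include SDH4 (1.79) and MDH1 (1.33). Mitochondrial ribosomal protein genes rose in 41 of 62 cases and fell in 2 (41 and 2 adjusted over the list alone). The median was 0.29 (adjusted p = 1.1e-04, and adjusted p = 0.442 with an estimated correlation). Members include MRP49 (0.72). Methionine and sulphur assimilation had 18 of 30 genes higher and 5 lower (18 and 5 adjusted over the list alone). Their median was 0.30 (adjusted p = 0.0048, and adjusted p = 0.477 with an estimated correlation). The sulphate permease gene SUL2 (2.83) and MET5 (2.36) had the largest rises. Among nitrogen catabolite repressed genes, 16 of 21 rose and 3 fell (16 and 3 adjusted over the list alone). The median was 0.61 (adjusted p = 0.0018, and adjusted p = 0.442 with an estimated correlation). APE1 (1.67) and the general amino acid permease gene GAP1 (1.43) are examples.

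Growth-related groups were lower in W303 at pH 4.5. Cytosolic ribosomal protein genes fell in 106 of 129 cases and rose in 1 (107 and 1 adjusted over the list alone). Their median was -0.36 (adjusted p = 1.4e-12, and adjusted p = 0.477 with an estimated correlation). RPL9A and RPS22B fell most, with log2 ratios of -0.84 each. Ribosome biogenesis genes fell in 62 of 70 cases and rose in 4 (62 and 5 adjusted over the list alone). The median was -0.47 (adjusted p = 4.9e-10, and adjusted p = 0.539 with an estimated correlation). ERB1 fell by 0.81, while NOP1, the fibrillarin gene of the same list, rose by 2.13 ± 0.074 (SE, n = 4). Purine and one-carbon genes fell in 16 of 18 cases and rose in 1 (16 and 1 adjusted over the list alone). Their median was -1.25 (adjusted p = 2.0e-08, and adjusted p = 0.442 with an estimated correlation). Sterol biosynthesis genes fell in 24 of 27 cases and rose in 0 (24 and 0 adjusted over the list alone). The median was -0.58 (adjusted p = 3.1e-08, and adjusted p = 0.254 with an estimated correlation). Members include ERG25 (-1.27) and HMG1 (-1.10). Potassium and sodium transport genes rose in 12 of 20 cases and fell in 5 (13 and 5 adjusted over the list alone), and the list was not called (median 0.23, adjusted p = 0.37); the kinase gene PTK2 (0.95) and the phosphatase inhibitor gene VHS3 (0.85) rose most. Of the 43 lists, 10 were called higher and 4 lower.

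Fewer genes passed the test in W303 at pH 6.0, with GPG1 again at the top, auxotrophic markers such as HIS3 left out, at 9.41-fold (log2 3.23 ± 0.11 SE, n = 4, adjusted p = 8.4e-04). YGP1 rose 6.69-fold (log2 2.74 ± 0.30 SE, n = 4, adjusted p = 0.018), YRO2 (YBR054W) 6.40-fold (log2 2.68 ± 0.13 SE, n = 4, adjusted p = 0.0036), SPI1 4.97-fold, HSP12 4.47-fold and PUT1 3.51-fold (n = 3). DED1 (YOR204W), the serine biosynthesis gene SER3 (YER081W), the peroxisomal citrate synthase gene CIT2 (YCR005C) and the lactate dehydrogenase gene CYB2 (YML054C) rose 3.27-fold, 3.17-fold, 3.15-fold and 3.11-fold. LEU1 was 5.05-fold lower (log2 -2.34 ± 0.14 SE, n = 4, adjusted p = 0.0040) and ARO9 4.17-fold lower (log2 -2.06 ± 0.23 SE, n = 4, adjusted p = 0.018). BTN2 (YGR142W), the mitochondrial carrier gene OAC1 (YKL120W), the uridine permease gene FUI1 (YBL042C), the alpha-factor protease gene BAR1 (YIL015W), ARO10 (YDR380W, n = 3) and PDR5 had log2 ratios of -1.78, -1.59, -1.52, -1.45, -1.40 and -1.39. With a dye term in the fit of the 4 arrays, BTN2 and ARO10 were not called. HSP82 (YPL240C) and BAP2 were at -1.37 and -1.36. By the rule for naming them, each of these 20 genes had 1 sign on every array that measured it.

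At pH 6.0, limma called 163 of 4856 genes, 93 higher and 70 lower, and 58 of them by at least 2-fold, 33 higher and 25 lower. The count rests on single arrays. Leaving out replicate 1, 2, 3 or 4 gave 1, 24, 319 and 2 calls, so named calls depended on replicate 1, 2 or 4, although 0 of the called named genes turned sign. Arrays 1 and 4 alone, taken after the number of values was seen, gave 340 calls, array weights 479, SAM 333, and a fit of all 12 arrays 1097.

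Chaperones of the heat shock response were lower at pH 6.0. There, 11 of 24 genes fell and 0 rose (14 and 1 adjusted over the list alone). Their median was -0.54 (adjusted p = 1.9e-09, and adjusted p = 0.427 with an estimated correlation). Members include the near-identical HSP82 (-1.37) and HSC82 (-1.20), whose single values are uncertain, and SSA2 (-1.32). Purine and one-carbon genes fell in 8 of 17 cases and rose in 0 (13 and 0 adjusted over the list alone). The median was -0.67 (adjusted p = 1.7e-10, and adjusted p = 0.427 with an estimated correlation). Members include GCV2 (-1.25) and ADE1 (-1.06). Sterol biosynthesis genes fell in 1 of 27 cases and rose in 0 (5 and 0 adjusted over the list alone). Their median was -0.24 (adjusted p = 3.3e-04, and adjusted p = 0.593 with an estimated correlation). That 1 gene was ERG27 (-0.53), which was not called with a dye term in the fit of the 4 arrays, with scaling between arrays or on arrays 1 and 4 alone.

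The respiratory chain and ATP synthase list was higher at pH 6.0, with 3 of 32 genes called higher and 0 lower (18 and 0 adjusted over the list alone) and a median of 0.44 (adjusted p = 1.7e-10, and adjusted p = 0.449 with an estimated correlation), among them NDI1 (1.02 ± 0.092 SE, n = 4) and COX4 (0.71). General stress genes rose in 4 of 31 cases and fell in 0 (11 and 0 adjusted over the list alone). The median was 0.28 (adjusted p = 3.3e-05, and adjusted p = 0.587 with an estimated correlation). Trehalose and glycogen genes rose in 3 of 15 cases and fell in 0 (3 and 0 adjusted over the list alone). Their median was 0.41 (adjusted p = 0.0012, and adjusted p = 0.427 with an estimated correlation). In the phosphate regulon, 1 of 15 genes rose and 0 fell (7 and 0 adjusted over the list alone). The median was 0.39 (adjusted p = 0.0029, and adjusted p = 0.605 with an estimated correlation). That gene, the acid phosphatase gene PHO5, rose by 1.56 ± 0.12 (SE, n = 4, adjusted p = 0.0072), and its near-identical neighbour PHO3 by 1.15 ± 0.18 (SE, n = 4, adjusted p = 0.036). Without replicate 1 or 4, PHO5 was 1.55 and 1.48 and no longer called (adjusted p = 0.145 and 0.085). Potassium and sodium transport genes had 0 of 19 members called (0 adjusted over the list alone) and a median of 0.03 (adjusted p = 0.76). Of the 43 lists, 11 were called higher and 8 lower.

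**Figure D2:**
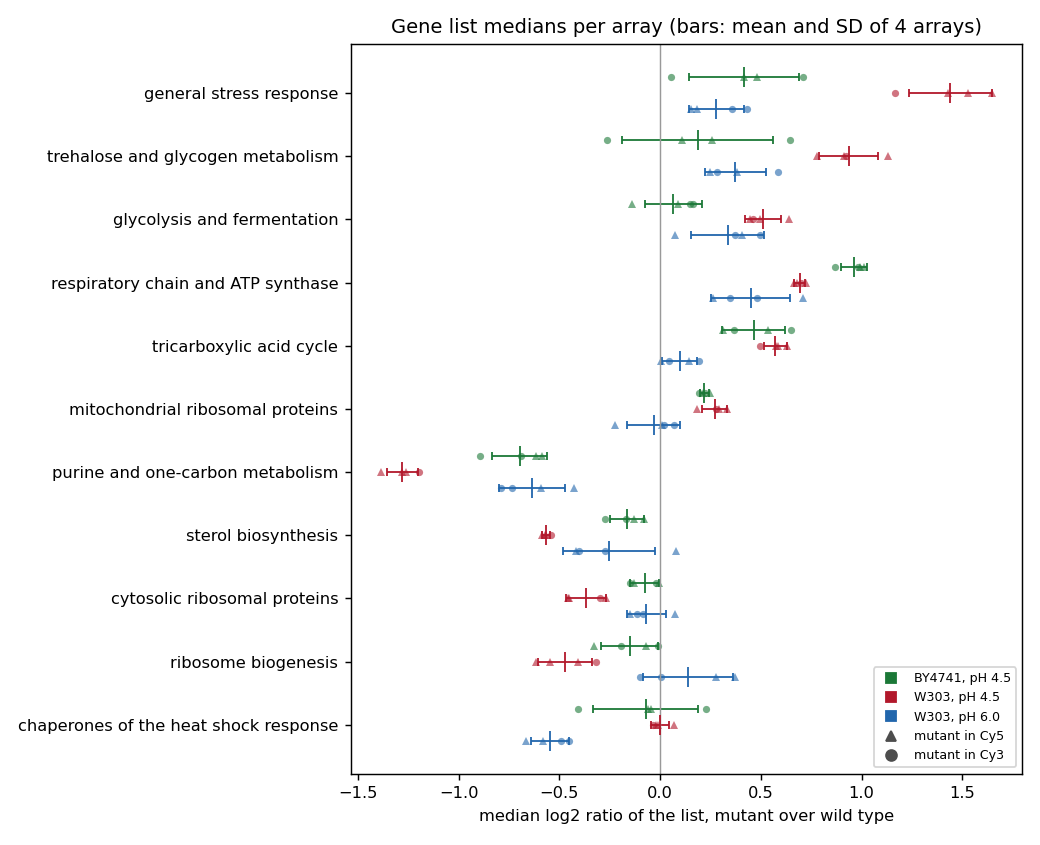
Median log2 ratio of mutant over wild type of 11 gene lists on each array of the 3 sets, with triangles for arrays with the mutant in Cy5, circles for arrays with the mutant in Cy3, and bars for the mean and SD of the 4 arrays. The respiratory chain medians lie above 0 on all 12 arrays, from 0.26 to 1.01, and the purine and one-carbon medians below 0 on all 12, from -1.38 to -0.43.

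Effects were correlated between the sets across genes, which are not independent replicates. The 3 Pearson correlations were 0.678 (Spearman 0.614, 5278 genes) between BY4741 and W303 at pH 4.5, 0.603 (Spearman 0.505, 4840 genes) between the W303 sets, and 0.514 (Spearman 0.392, 4765 genes) between BY4741 and W303 at pH 6.0. Over genes called in neither set of a pair they were far lower, as given under the processing. Between BY4741 and W303 at pH 4.5, 665 genes rose in both sets, against 308 for independent lists, 596 fell in both, against 273, and 96 were called in opposite directions, against 579. Over the 4755 genes tested in all 3 sets, 64 rose in every set, against 5.23 for independent lists, and 43 fell, against 3.68. GPG1, HSP12, SPI1, LEU1, ARO9, BAP2 and ADE2 were called in the same direction in all 3.

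The difference of the mutant effect between the backgrounds at pH 4.5 was tested directly. The quantity is the log2 ratio of mutant over wild type in W303 minus that in BY4741, and no array compares the backgrounds themselves. The mutant effect on general stress genes was higher in W303 as a group, with the ratio of 19 of 31 genes higher and of 2 lower (20 and 2 adjusted over the list alone), a median difference of 0.67 (adjusted p = 1.5e-06, and adjusted p = 0.587 with an estimated correlation). SPI1 differed by 2.74 ± 0.48 (SE, 12 arrays, adjusted p = 0.0031), GPG1 by 2.16 ± 0.31 (SE, adjusted p = 8.4e-04) and HSP12 by 2.04 ± 0.27 (SE, adjusted p = 5.3e-04). With scaling between arrays these 3 were 1.55, 0.61 and 0.73 and no longer called (adjusted p = 0.11, 0.40 and 0.20). The list tests were not run with scaling, so the list differences were not checked under it. GAD1, for glutamate decarboxylase, differed by 2.27, the chaperone gene SSE2 by 1.97 and GAP1 by 1.95 ± 0.15 (SE, adjusted p = 7.4e-06), and SUL2 by 2.02. FIT3, a cell wall gene of iron uptake, differed by 1.96 ± 0.23 (SE, adjusted p = 2.3e-04), from -0.66 in BY4741 to 1.30 in W303.

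The mutant effect was also higher in W303 for carbon reserve and glycolysis genes. In trehalose and glycogen metabolism, the ratio was higher for 9 of 15 genes and lower for 1 (11 and 1 adjusted over the list alone). The median difference was 0.88 (adjusted p = 2.6e-05, and adjusted p = 0.587 with an estimated correlation). PGM2 differed by 1.97 and GDB1 by 1.90. In glycolysis and fermentation, it was higher for 16 of 21 genes and lower for 0 (18 and 0 adjusted over the list alone). Their median difference was 0.52 (adjusted p = 3.3e-07, and adjusted p = 0.587 with an estimated correlation). The effect on the respiratory chain list was smaller in W303, with a higher ratio for 2 of 31 genes and a lower one for 7 (2 and 12 adjusted over the list alone) and a median difference of -0.32 (adjusted p = 6.3e-04, and adjusted p = 0.587 with an estimated correlation).

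For cytosolic ribosomal protein genes the ratio of mutant over wild type was lower in W303 in 37 of 127 cases and higher in 0 (41 and 0 adjusted over the list alone). The median difference was -0.23 (adjusted p = 9.5e-12, and adjusted p = 0.587 with an estimated correlation). For purine and one-carbon genes it was lower in 9 of 17 cases and higher in 2 (10 and 3 adjusted over the list alone). Their median difference was -0.41 (adjusted p = 8.8e-05, and adjusted p = 0.587 with an estimated correlation). In all, the mutant effect on 971 of 4755 genes differed between the backgrounds by limma, with the ratio higher in W303 for 517 and lower for 454. Which direction had more genes depended on the normalisation, since median centring gave 454 higher and 509 lower. Scaling between arrays gave 426 (209 higher and 217 lower), the 8 arrays of these groups alone 2012 and array weights 2213, while leaving out 1 array gave 552 (BY4741 replicate 4), 550 (W303 pH 4.5 replicate 3), 488 (W303 pH 4.5 replicate 4) and 1569 (W303 pH 6.0 replicate 3, which enters through the shared spread).

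The difference of the mutant effect between pH 6.0 and pH 4.5 in W303 was tested in the same way, as the log2 ratio of mutant over wild type at pH 6.0 minus that at pH 4.5. For ribosome biogenesis genes the ratio was higher at pH 6.0 in 47 of 68 cases and lower in 2 (55 and 2 adjusted over the list alone). The median difference was 0.64 (adjusted p = 8.2e-17, and adjusted p = 0.350 with an estimated correlation). For cytosolic ribosomal protein genes it was higher in 30 of 127 cases and lower in 0 (31 and 0 adjusted over the list alone). Here the median difference was 0.24 (adjusted p = 6.9e-11, and adjusted p = 0.350 with an estimated correlation). For purine and one-carbon genes it was higher in 10 of 17 cases and lower in 0 (14 and 0 adjusted over the list alone). Their median difference was 0.48 (adjusted p = 5.7e-08, and adjusted p = 0.350 with an estimated correlation). HPT1 differed by 2.15 ± 0.13 (SE, 12 arrays, adjusted p = 1.3e-06) and ADE17 by 2.04 ± 0.18 (SE, adjusted p = 3.6e-05). In the phosphate regulon the ratio was higher for 4 of 14 genes and lower for 0 (5 and 0 adjusted over the list alone). The median difference was 0.42 (adjusted p = 1.3e-04, and adjusted p = 0.350 with an estimated correlation). PHO5 differed by 2.09 ± 0.12 (SE, adjusted p = 1.3e-06), from -0.54 at pH 4.5 to 1.56 at pH 6.0, and PHO3 by 2.15 ± 0.18 (SE, adjusted p = 1.2e-05).

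Ratios of mutant over wild type in stress groups were lower at pH 6.0 than at pH 4.5. Those of general stress genes were lower in 19 of 31 cases and higher in 0 (21 and 0 adjusted over the list alone). Their median difference was -0.75 (adjusted p = 1.2e-07, and adjusted p = 0.350 with an estimated correlation). Ratios of chaperones were lower in 15 of 22 cases and higher in 0 (18 and 0 adjusted over the list alone). The median difference was -0.79 (adjusted p = 2.8e-07, and adjusted p = 0.350 with an estimated correlation). Those of mitochondrial ribosomal protein genes were lower in 25 of 58 cases and higher in 0 (30 and 0 adjusted over the list alone). Their median difference was -0.31 (adjusted p = 6.3e-07, and adjusted p = 0.350 with an estimated correlation). Ratios of trehalose and glycogen genes were lower in 9 of 15 cases and higher in 0 (11 and 0 adjusted over the list alone). The median difference was -0.69 (adjusted p = 3.7e-04, and adjusted p = 0.517 with an estimated correlation). FMP33, a mitochondrial protein gene, differed by -2.22 ± 0.26 (SE, adjusted p = 2.4e-04), from 2.59 to 0.37, and MDH2, for cytosolic malate dehydrogenase, by -1.96 ± 0.14 (SE, adjusted p = 5.2e-06), from 1.30 to -0.66. PGM2 differed by -1.94. SPI1 (-2.12), HSP12 (-2.01) and RGI1 (-1.94) were called, but with scaling between arrays they were -1.14, -1.10 and -1.59 and no longer called (adjusted p = 0.21, 0.056 and 0.079). List differences between the pH values were not tested with scaling.

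Between the pH values, the mutant effect on 1139 of 4755 genes differed by limma, with the ratio higher at pH 6.0 for 511 and lower for 628, against 564 and 556 with median centring. In simulated data with the spread of each gene but independent noise and few changed genes, 57 of 224 such calls were false. Scaling between arrays gave 580 (253 higher and 327 lower), and leaving out W303 pH 4.5 replicate 4 gave 745.

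**Figure D3:**
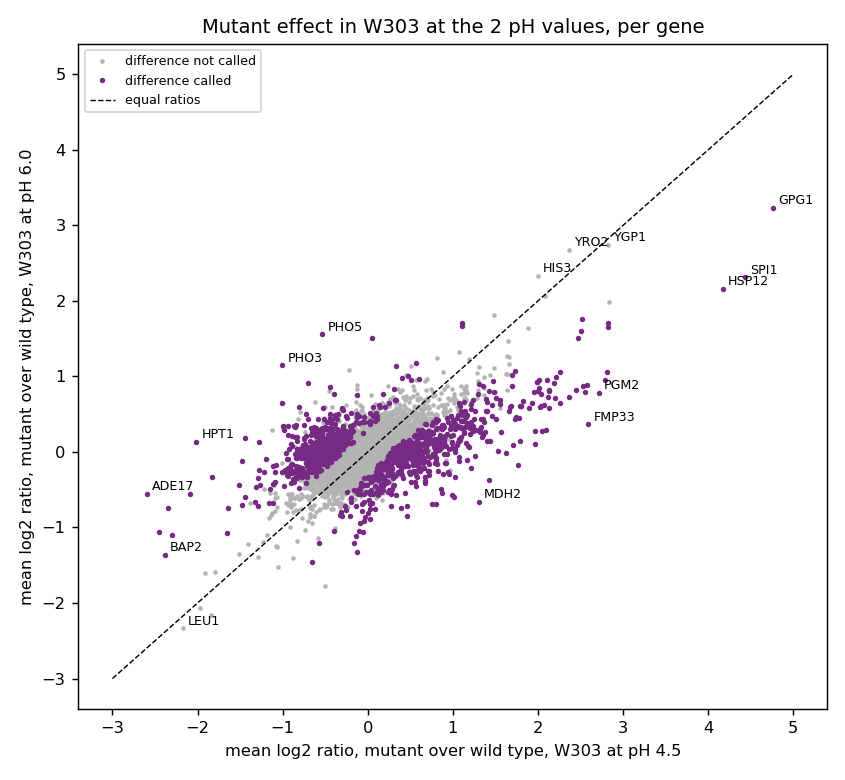
Mean log2 ratio of mutant over wild type at pH 6.0 (vertical axis) against that at pH 4.5 (horizontal axis) in W303, with 1 point per gene tested in both sets, purple points for genes whose difference was called, and a dashed line of equal ratios. The slope of the pH 6.0 means on the pH 4.5 means over the 4840 genes is 0.387.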

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

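Among the tests in this part, the test of the genes around HIS3, the test of the other histidine genes at pH 4.5 and the test of MF(ALPHA)2 were chosen only after the result was seen.

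HIS3 and its neighbour DED1 rose in both W303 sets, while in BY4741 HIS3 was not called and DED1 fell. YOR203W, the open reading frame numbered between them, moved with HIS3 where it was measured. Its log2 ratio lay between 1.82 and 2.32 in W303 at pH 4.5 and between 1.55 and 2.70 at pH 6.0. In BY4741 it lay between -0.16 and 0.18. General activation of amino acid genes through Gcn4 is argued against at pH 4.5, where HIS1, HIS4, HIS5 and HIS7 had a median log2 ratio of -0.64 while HIS3 rose. These genes do not decide it at pH 6.0, where their median was 0.22 and the arrays spread widely. The median of the whole Gcn4 target list, taken up afterwards, averaged 0.03 ± 0.052 (SD, n = 4 arrays) at pH 6.0. That argues against a general activation of the list there. A candidate explanation is a HIS3 marker, with flanking DNA, in the W303 mutant. The genes 2 to 4 places from HIS3 had a median of -0.0845 at pH 4.5, as a short fragment would leave them. A regulatory change limited to HIS3, YOR203W and DED1 would leave them so too, and the disruption construct is not given in the sources used here. MRM1, on the other side of HIS3, was called in BY4741 (0.46) as well as in W303 at pH 4.5 (0.70), so it does not separate these.

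MF(ALPHA)1, made by alpha cells, was 8.33-fold higher in the W303 mutant at pH 4.5 (n = 3), and BAR1, made by a cells, was lower in all 3 sets, by 0.42 in BY4741, 0.66 in W303 at pH 4.5 and 1.45 at pH 6.0, so its fall is not particular to W303. Opposite mating types of mutant and wild type would lower all a-specific genes by a large amount, but 7 of them had a median of 0.88 at pH 4.5, with 4 called higher and 3 lower, although the 5 measured at pH 6.0 had a median of -0.44 (adjusted p = 0.014, and adjusted p = 0.557 with an estimated correlation). Loss of silencing or a diploid state would lower the haploid genes GPA1, STE18 and FUS3, whose median was 0.17 at pH 4.5. Signal shared with the related gene MF(ALPHA)2 is argued against, since that gene would have to rise as well and its mean at pH 4.5 was -0.163 ± 0.139 (SE, n = 4), against 3.06 ± 0.113 (SE, n = 3) for MF(ALPHA)1. A small share of alpha cells in the mutant cultures was not tested and stays open, although SAG1, another gene of alpha cells, was lower at pH 4.5 (-0.33, adjusted p = 0.042). No biological explanation given by the design was tested.

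Fewer genes were called at pH 6.0 than at pH 4.5 in W303. Among the 4840 genes tested at both, 163 were called at pH 6.0 and 3363 at pH 4.5, so fewer measured genes do not account for it. Leaving out pH 6.0 replicate 3, which has the fewest values, gave 319 calls over genes with at least 2 values. The pH 4.5 set with 1 array left out, under the same filter, gave 3243 to 3780, still far more. With 1 spread shared by all 12 arrays the counts were 1097 at pH 6.0 and 2924 at pH 4.5, a narrower gap. That fit also estimates the spread from more arrays, so the part due to the wider spread at pH 6.0 is not separated. A wider spread between arrays alone would leave the mean ratios as large as at pH 4.5, but over 1536 genes called in BY4741 the slope of the pH 6.0 means on the pH 4.5 means was 0.441. That slope was at most 0.458 and at least 0.420 with any 1 of the W303 arrays left out, as smaller effects at pH 6.0 would give. Effects on partly different genes would also lower the slope, and the genes were chosen by calls at pH 4.5, so it does not separate these. Over all genes tested in each set, the median absolute log2 ratio was 0.17 at pH 6.0 and 0.30 at pH 4.5. Compression of the ratios by weak signal on the pH 6.0 arrays could give the same slope and stays open, since no intensities were used here.

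Single arrays stood apart from the other 3 of their set in 8 of 134 gene results tested, and chance gives about 1 in 20. HIS4 was -1.51 on BY4741 replicate 4. HMG1 was -0.73 on BY4741 replicate 2. ADE2 was -0.43 on BY4741 replicate 4. ADE13 was -2.14 on W303 pH 4.5 replicate 3. GLC3 was 2.41 on W303 pH 4.5 replicate 4. HAL5 was 0.42 on W303 pH 4.5 replicate 1. YGP1 was 1.58 on W303 pH 6.0 replicate 2. NOP1 was 0.93 on W303 pH 6.0 replicate 3. List medians stood apart for nitrogen catabolite repressed genes on W303 pH 6.0 replicate 4 (0.38), for the cell wall integrity response on BY4741 replicate 4 (0.065) and W303 pH 4.5 replicate 2 (0.019), and for the proteasome on BY4741 replicate 1 (-0.058).

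The limma test of the difference in mutant effect called these named genes between W303 and BY4741 at pH 4.5, values being the log2 ratio of mutant over wild type in W303 minus that in BY4741. The stress, carbon and iron genes were SPI1 (2.74), GAD1 (2.27), GPG1 (2.16), HSP12 (2.04), PGM2 (1.97), SSE2 (1.97), FIT3 (1.96), GDB1 (1.90), GLK1 (1.78), GLC3 (1.33), HXK1 (1.16), GPX2 (1.14) and YRO2 (0.58). Sulphur, nitrogen and marker genes were SUL2 (2.02), GAP1 (1.95), HIS3 (1.85), MET17 (1.77), MET5 (1.01), CAN1 (0.85), APE1 (0.82), MET16 (0.54), GCV2 (0.49) and PUT1 (-0.59). Strain genotypes were not used, so differences of the marker genes, such as HIS3 and MET17, need not be mutant effects. Of other genes, NOP1 (1.22), VHS3 (0.93), PTK2 (0.83), PDR5 (0.71), AQR1 (0.62), QDR2 (0.44) and NDI1 (0.39) were higher. Lower ones were ERG13 (-0.37), RPL9A (-0.49), QCR7 (-0.54), QCR8 (-0.55), ERG25 (-0.72), ATP19 (-0.85) and PTR2 (-1.88). Ratios of purine genes were lower, namely ADE57 (-1.39), HPT1 (-1.43), ADE13 (-1.49), ADE2 (-1.73), ADE1 (-1.73) and ADE17 (-1.83).

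Lists whose mutant effect differed between the backgrounds, by median difference, were trehalose and glycogen (0.88), general stress (0.67), glycolysis and fermentation (0.52), Yap1 targets (0.19), cytosolic ribosomal proteins (-0.23), the respiratory chain (-0.32), ribosome biogenesis (-0.32), sterol biosynthesis (-0.37) and purine metabolism (-0.41). Their adjusted p lay between 9.5e-12 and 0.027, and was 0.587 for each with an estimated correlation. Yap1 targets were not called without W303 pH 4.5 replicate 1 (adjusted p = 0.053).

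Between pH 6.0 and pH 4.5 in W303, values being the ratio at pH 6.0 minus that at pH 4.5, the same test called the ratios of PHO3 (2.15), PHO5 (2.09), BAP2 (1.03), ERG25 (1.03), ERB1 (0.81), RPS22B (0.76), DED1 (0.61), RPL9A (0.57) and SER3 (0.56) higher. Ratios of purine genes were higher, namely HPT1 (2.15), ADE17 (2.04), ADE13 (1.60), ADE57 (1.53), ADE1 (1.40) and ADE2 (1.19). Ratios of stress and carbon genes were lower, namely SPI1 (-2.12), HSP12 (-2.01), RGI1 (-1.94), PGM2 (-1.94), GLK1 (-1.69), GDB1 (-1.66), HXK1 (-1.61), GPG1 (-1.53) and GLC3 (-1.49). So were the mitochondrial and metabolic genes FMP33 (-2.22), MDH2 (-1.96), SDH4 (-1.17), CIT2 (-1.17), MRP49 (-1.02), MDH1 (-0.89) and NDI1 (-0.68), and the chaperones SSA2 (-1.20) and HSC82 (-1.04). Other lower genes were GAP1 (-1.80), MET5 (-1.64), NOP1 (-1.33), MET17 (-1.31), APE1 (-1.08), PTK2 (-0.92), URA3 (-0.87), BAR1 (-0.79) and CLN1 (-0.42).

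Lists whose mutant effect differed between the pH values, by median difference, were ribosome biogenesis (0.64), purine metabolism (0.48), the phosphate regulon (0.42), sterol biosynthesis (0.35), cytosolic ribosomal proteins (0.24) and Gcn4 targets (0.16), with higher ratios at pH 6.0. Lower ones were the proteasome (-0.30), mitochondrial ribosomal proteins (-0.31), the tricarboxylic acid cycle (-0.34), hexose transporters (-0.52), trehalose and glycogen (-0.69), general stress (-0.75) and chaperones (-0.79). Adjusted p-values lay between 8.2e-17 and 0.031, and between 0.350 and 0.597 with an estimated correlation. Hexose transporters were not called without W303 pH 6.0 replicate 1 (adjusted p = 0.070) or replicate 3 (adjusted p = 0.060).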

How the results depend on the processing

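The alternatives chosen after seeing the data are camera itself on complete genes, lists with a dye term or with 1 array left out, correlations with 1 array left out, and the runs without W303 pH 6.0 arrays 2 and 3. Across alternatives, named genes other than SAT4 and HAL5 kept their direction and side of the threshold in 2153 cases. They lost a call in 102, gained one in 20 and turned sign in 6. For SAT4 and HAL5 these counts were 53, 8, 1 and 5. For lists they were 2437, 122, 105 and 2, but a list that turned while called in neither result was counted as kept. The 2 list cases counted as turned leave out such turns. No called named gene turned. Signal over background, which limits array values, is unknown here. Where no cause is named, the cause was not tested.

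A minimum of 1.5-fold left 358 calls in BY4741 and 1119 in W303 at pH 4.5, by construction. Columns left unturned gave 0 calls in each set by limma (260, 169 and 171 at an unadjusted p below 0.05, and 2, 57 and 0 by SAM). In W303 at pH 6.0 the joint fit gave 1097, the joint fit with a dye term 1184, array weights 479, arrays 1 and 4 alone 340 and SAM 333. The difference between backgrounds gave 426 calls with scaling between arrays, 2012 with 8 arrays and 2213 with array weights, and that between pH values 580 with scaling. In simulated data 8.91% and 16.8% of the calls with array weights were false for these 2 differences. With each array left out, calls ranged from 754 to 1389 in BY4741, 3243 to 3780 in W303 at pH 4.5, 1 to 319 in W303 at pH 6.0, 488 to 1569 for the backgrounds and 745 to 1549 for the pH values. A replicate block gave 717 and 986 for the differences. Residuals of arrays of equal number correlated between -0.142 and 0.241, and those of unequal number reached 0.313. These low values neither show nor exclude a pairing by number.

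HAL5 in BY4741 ranged from -0.67 to -0.41 with 1 array left out and lost its call without replicate 1, 3 or 4 (-0.41, -0.49 and -0.45). At pH 4.5 in W303 it ranged from -0.27 (without replicate 1, when it was called) to -0.020. At pH 6.0 its mean turned to 0.026 with a dye term, 0.041 with array weights and 0.0185 on arrays 1 and 4, and ranged from -0.14 to 0.0335 with 1 array left out, above 0 without replicate 2 or 4 (0.0185 and 0.0335). SAT4 in W303 at pH 4.5 had -0.17 (adjusted p = 0.62) in the joint fit and -0.31 (adjusted p = 0.37) with its dye term, and ranged from -0.20 to -0.15 with 1 array left out, not called without replicate 2, 3 or 4. Uncalled values also turned for URA3 in W303 at pH 4.5 (0.036 with a dye term in the joint fit, 0.041 with array weights, 0.038 without replicate 2, the left-out range being -0.13 to 0.038), and in W303 at pH 6.0 for TRP1 (0.012 on arrays 1 and 4, range -0.47 to 0.30, above 0 without replicate 2) and DMC1 (range -0.12 to 0.33, below 0 without replicate 3). With fry, Yap1 targets in BY4741 (median 0.081, adjusted p = 0.027) and sporulation genes in W303 at pH 4.5 (0.086, adjusted p = 0.013) were called downward.

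With an estimated correlation 0 lists were called in each of the 5 comparisons (2, 2, 4, 2 and 4 at an unadjusted p below 0.05), and fry, which asks whether a list moves at all, called 28, 34, 12, 15 and 24. With each array left out, called lists ranged from 19 to 23, 13 to 14, 15 to 19, 8 to 12 and 13 to 15. The correlations between sets were 0.614, 0.505 and 0.392 by Spearman, and 0.0994, 0.127 and 0.188 over genes called in neither set. Over genes called in either they were 0.646 between the W303 sets and 0.638 between BY4741 and W303 at pH 6.0. With each array left out the Pearson correlations ranged from 0.625 to 0.692, 0.539 to 0.597 and 0.444 to 0.509. They took genes with at least 2 values in every set, so the filter changed together with the arrays.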

Other observations

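Histone and G1 to S phase genes were higher as groups in some sets. The G2 to M phase list was not called in BY4741 (0 of 7 genes rose and 1 fell, adjusted p = 0.91). Its median averaged 0.02 over the BY4741 arrays, 0.17 in W303 at pH 4.5 and 0.12 at pH 6.0. In BY4741, histone genes rose in 7 of 8 cases (8 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.0014, and adjusted p = 0.607 with an estimated correlation), HHF1 for example by 0.49. In W303 at pH 4.5 histone genes rose in 6 of 8 cases, with a median of 0.29, and the list was not called (adjusted p = 0.10). At pH 6.0 it was called (median 0.16, adjusted p = 0.048, and adjusted p = 0.619 with an estimated correlation) with 0 of 8 genes called, and not without replicate 2 or 3 (adjusted p = 0.32 and 0.096). Its difference between the pH values was not called (adjusted p = 0.47). At pH 6.0 in W303, G1 to S phase genes rose in 3 of 7 cases (3 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.013, and adjusted p = 0.449 with an estimated correlation), including the cyclin genes CLN1 (0.89) and PCL1 (0.78). The list was not called in the other sets, although CLN1 (0.93 in BY4741 and 1.31 in W303 at pH 4.5) and PCL1 (0.45 and 0.86) were called higher there too. Its difference was called neither between the backgrounds nor between the pH values. The G1 to S list was not called without replicate 2 (adjusted p = 0.10) or without replicate 3 (adjusted p = 0.086), and CLN1 and PCL1 were not called without replicate 1, 2 or 4 (CLN1 0.94, 0.85 and 0.90, PCL1 0.78, 0.84 and 0.80).

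Drug efflux and calcium-regulated genes moved as well. Pleiotropic drug resistance genes fell in 6 of 9 cases in BY4741 and rose in 0 (6 and 1 adjusted over the list alone), with a median of -0.69 (adjusted p = 0.0042, and adjusted p = 0.468 with an estimated correlation), PDR5 and TPO1 in the lead. In the W303 set at pH 6.0 they fell in 1 of 9 cases (5 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.0012, and adjusted p = 0.587 with an estimated correlation), while in W303 at pH 4.5 they fell in 5 of 10 cases and rose in 3 and the list was not called (adjusted p = 0.20). The test of the difference called this list neither between the backgrounds nor between the pH values. Calcineurin and Crz1 targets rose in 4 of 12 cases in BY4741 (6 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.0051, and adjusted p = 0.607 with an estimated correlation). In W303 at pH 4.5 they rose in 8 of 12 cases and fell in 3, with a median of 0.32 and no call of the list (adjusted p = 0.12), and the difference between the backgrounds was not called (median -0.04, adjusted p = 0.73). At pH 6.0 the list was not called either (adjusted p = 0.31). The proteasome list was lower in W303 at pH 6.0, with 0 of 32 genes called (0 adjusted over the list alone) and a median of -0.21 (adjusted p = 3.3e-05, and adjusted p = 0.427 with an estimated correlation). It was lower in BY4741 too (median -0.13, adjusted p = 0.017, and adjusted p = 0.535 with an estimated correlation) and not called in W303 at pH 4.5 (adjusted p = 0.78).

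Other groupings of the arrays were tried for each count of called genes. Turning the sign of single arrays gives 8 patterns per set, too few for a share under 0.05. The real pattern gave 1714, 3807 and 163 calls in BY4741, W303 at pH 4.5 and W303 at pH 6.0, and the highest of the other patterns 0 by limma (264, 169 and 523 genes at an unadjusted p below 0.05, against 2405, 3950 and 946). For the differences, 1 of 35 splits of the 8 arrays into 4 and 4, the real one, gave as many calls, so chance can be excluded only at a share of 1 in 35, and mixed splits carry the real difference in their spread, which lowers their counts. The real splits gave 971 calls for the backgrounds and 1139 for the pH values, and the highest of the other splits 0 by limma (462 and 1074 genes at an unadjusted p below 0.05, against 1626 and 1801).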
